A study of Caenorhabditis elegans with 4 samples.

How the data were processed

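The series measured binding of GFP-tagged MAB-5 in *C. elegans* hermaphrodites at the L2 stage, in 2 ChIP samples and 2 input samples. Per the labels' protocols, worms were synchronised as starved first-stage larvae, grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and a part of each extract was kept as input chromatin. The remainder was precipitated with affinity-purified antibodies against GFP. Groups and replicate numbers were taken from the sample titles.

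The analysis started from 3 lists of regions, 1 for each ChIP sample and 1 combined list. Per the file headers the coordinates are those of WormBase build WS180, and the source column of each list names PeakSeq, a peak caller that scores ChIP reads against input. The aligner, the settings of the caller, the q value limit and the way the combined list was made are not given in the sources used here. Each deposited entry held 1 measurement, a q-value given by the authors, in which a smaller value means more significant enrichment, not necessarily a higher one. No list held read counts, heights or fold enrichments, so depth per sample is unknown, and a shorter list or larger q values in a replicate can come from fewer reads as well as from weaker binding. Strength was computed as −log10 of the q-value and was used to describe, rank and divide regions within a list. Across lists it was used for the planned correlation and for the ratio of paired strengths. Of columns with values of other samples there were 0.

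Entries of the replicate lists were used as deposited in the planned comparisons. Since many entries of a list overlapped, the comparisons were repeated on distinct regions, made by joining overlapping entries of a list and keeping the smallest q-value. This was added after the lists had been seen. Entries of 2 lists were called shared when they overlapped by at least 1 bp. Alternatives were a reciprocal overlap of at least 50% and region centres within 200 bp. Overlap was tested by circular shifts of 1 list within each chromosome's span (10000 shifts, one-sided), and by random placement as an alternative. The restriction to regions outside assembly gaps was not applied, since gap positions were not used here. Strengths of shared and unshared entries were compared by permutation of the difference of medians (100000 permutations, two-sided). Shares have exact Clopper-Pearson 95% binomial intervals, which cover counting error only. Correlations used Pearson's r on strengths, which are log values, and Spearman's rho over pairs in which each member overlapped only the other, with permutation p-values.

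Chromosome lengths of WS180 were not used here. The test of the share of regions on X against its share of the genome was therefore not run. The planned test of chromosome centres was run over the span between the first and the last base of any list on each chromosome, a choice made after the files had been seen. Families of tests over the 6 chromosomes were adjusted by the Benjamini-Hochberg method. The gene table at hand belonged to another build, WBcel235, so its coordinates were not joined to the regions. The planned tests of gene starts, of sequence motifs and of 24 gene lists were for that reason not run.

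The regions to be named were fixed before the data were examined as the nearest genes of the 10 strongest combined regions, or those regions by coordinates where no gene could be joined. The second form applied. Regions named outside this rule were chosen after their values were seen, and the text says so or presents them as exceptions or clusters. Spacing was tested by placing each combined region at random in its own 1 Mb window (1000 placements, one-sided). Placed regions were free to overlap, which raises the number of short gaps under random placement. Clusters were runs of regions with gaps of at most 5000 bp, and those with at least 5 regions were counted.

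The overlap test was tested on simulated data for the comparison of 976 replicate 1 entries with replicate 2. With 200 shared regions planted, 20 of 20 runs had a p under 0.05, and with none planted 0 of 20 did. The mean excess over the shifts in the planted runs was 194.9 entries. Entries of both simulated lists, apart from the planted ones, were placed independently at random. The double entries and close spacing of the real lists were not kept, so the simulation does not show how often the test errs on such lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with fixed random seeds. Alternatives also covered the 50% of each list with the smallest q values, each replicate list alone, regions in both replicate lists and a narrower definition of the chromosome centre.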

Results

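Binding of the transcription factor MAB-5 was mapped in *Caenorhabditis elegans* by chromatin immunoprecipitation followed by sequencing. MAB-5 is a Hox protein, a homeodomain regulator that gives posterior cells of the worm their identity and steers the migration of neuroblasts. The hermaphrodites carried a mab-5 transgene tagged with GFP and were collected at the second larval stage (L2) after growth at 20 °C. Chromatin was crosslinked with 2% formaldehyde and precipitated with an antibody against GFP. The series held 2 immunoprecipitated (ChIP) samples and 2 samples of input chromatin. A list of bound regions was analysed for each ChIP sample, together with 1 combined list, whereas no list of the input samples was analysed here. Each entry carried the authors' q value, and strength below means −log10 of that q value, a measure of significance rather than of the height of binding. The lists gave no read counts, heights or fold enrichments, so the sequencing depth of the libraries is unknown. The labels did not say that the replicates came from separate cultures. The p-values therefore measure only differences between lists or between regions, and regions are not independent replicates. Coordinates are those of the WS180 build named in the file headers, and no annotation of that build was used here, so regions are named by position and no gene is assigned to them.

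The combined list held 2261 separate MAB-5 regions, spread over all 6 nuclear chromosomes. Their median width was 419 bp (interquartile range 337 to 599 bp), and together they covered 1184741 bp. Widths ran from 5 to 6707 bp, and 4 regions were under 100 bp. The q values ran from 8.06e-242 to 0.000189 with a median of 3.30e-07. The replicate 1 list held 976 entries, which joined into 758 distinct regions covering 395836 bp. The replicate 2 list held 2652 entries, which joined into 2187 distinct regions covering 1156199 bp. Median widths of the entries were close in the 2 lists, at 430 bp in replicate 1 and 418 bp in replicate 2. The smallest q value was 2.27e-54 in replicate 1 and 8.06e-242 in replicate 2, and the medians were 8.86e-07 and 4.68e-07. The largest were 6.73e-05 and 0.000148. The lists thus ended at different q values, and the shares of regions found in the other list below compare lists with unlike limits. Overlapping entries were present in both replicate lists. In replicate 1, 218 distinct regions (28.8%) were made of 2 entries each. In replicate 2, 460 distinct regions (21.03%) were made of 2 or more entries. In the combined list no entry overlapped another.

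The 10 strongest regions of the combined list were named by rule, and the q values of all 10 also stood in the replicate 2 list. The strongest of all lay on chromosome III at 7777990 to 7784696, with a q value of 8.06e-242. It was 6707 bp wide, also the widest region of the list, and its strength of 241 was 1.91 times that of the region ranked next. In replicate 1 the strongest entry inside it ranked 4, with a strength of 44.9, below 3 regions at 53.6, 50.3 and 49.3. That next region lay on chromosome IV at 13695530 to 13696450, with a q value of 1.23e-126. Another of the 10 lay in its vicinity, at 13698975 to 13699964 (q = 2.32e-107). The remaining region on chromosome IV was 2220 bp wide, at 14032443 to 14034662 (q = 2.81e-124), and was the strongest region of the replicate 1 list with a q value there of 2.27e-54. Chromosome V held 1 of the 10, at 4506580 to 4508582 (q = 1.73e-88). The other 5 lay on the X chromosome. In order of strength they were at 11093733 to 11094612 (q = 6.38e-95), 14525395 to 14526294 (q = 2.55e-93), 13700413 to 13701105 (q = 8.49e-89), 8035747 to 8036880 (q = 6.60e-87) and 4208518 to 4209674 (q = 7.52e-83). All 10 overlapped a region in both replicate lists by at least 1 bp. With a reciprocal overlap of 50%, 9 of the 10 did, the exception being the strongest. Of the 10 strongest distinct regions of replicate 1, 7 overlapped the 10 strongest of replicate 2. The share of X among the 10 strongest was 50%, against 17.5% of the other 2251 regions. That difference had p = 0.0194 in a two-sided Fisher exact test and an adjusted p of 0.116 over 6 chromosomes, so it did not hold after Benjamini-Hochberg adjustment.

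The strongest region was listed differently in the 2 replicate lists, apart from 4 narrower sites that both held. In replicate 2 a single wide entry ran over the whole 6707 bp, with the same coordinates and q value as the combined entry. A further 4 narrower entries lay inside it. The 2 strongest of these were at 7779362 to 7781160 (q = 1.43e-35) and at 7783981 to 7784653 (q = 1.50e-35). In replicate 1 the same stretch held 4 distinct regions and no entry that spanned them. Each overlapped 1 of the 4 narrower replicate 2 entries. The strongest replicate 1 region was at 7779116 to 7781211 (q = 1.37e-45), followed by 7783980 to 7784674 (q = 2.85e-34). Within 20 kb on either side, the combined list held 9 other regions, the strongest at 7789078 to 7789850 (q = 2.64e-19). The strain carries the tagged mab-5 transgene in addition to the chromosomal gene, which belongs to chromosome III, and neither the input signal nor the position of mab-5 in this build was analysed here.

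**Figure D1:**
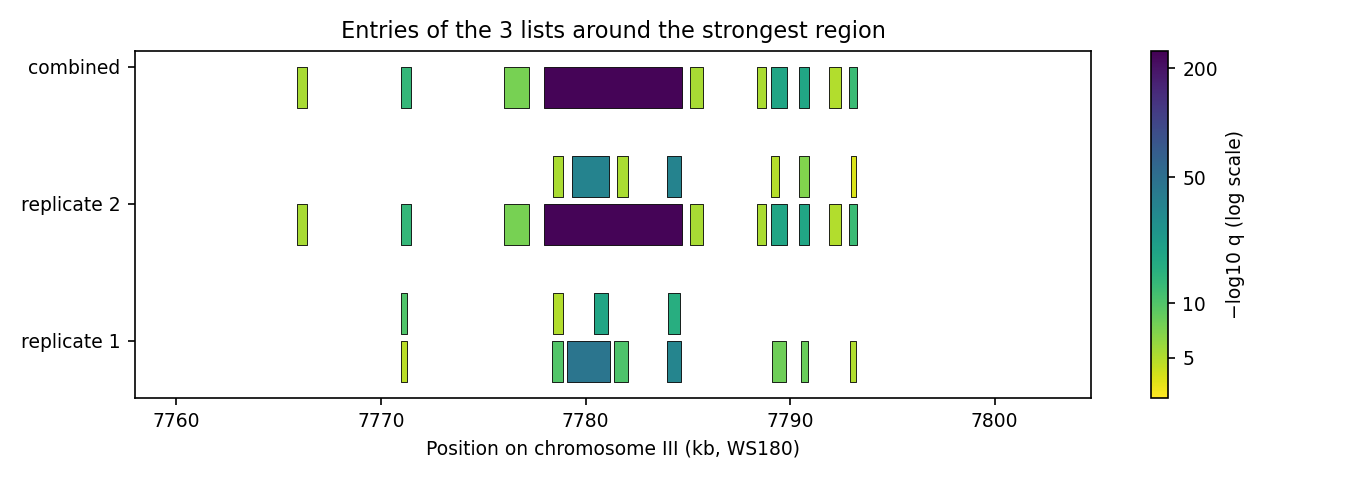
Entries of the combined, replicate 2 and replicate 1 lists within 20 kb of the strongest region, against position on chromosome III (kb, WS180). Each box is 1 entry coloured by −log10 q on a log scale, and overlapping entries of a list are drawn on separate levels. The wide box of the combined and replicate 2 lists covers 7 entries of replicate 1, which join into 4 distinct regions.

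The replicates were compared to find how many regions were listed in both. Nearly every region of the shorter list was found again in the longer one. Of the 976 entries of replicate 1, 970 overlapped an entry of replicate 2 by at least 1 bp, or 99.4% (exact 95% interval 98.7 to 99.8%). In the other direction, 1137 of the 2652 entries of replicate 2 overlapped replicate 1, or 42.9% (41.0 to 44.8%). Counted as distinct regions, which was chosen after the double entries were seen, the shares were 752 of 758 (99.2%) and 743 of 2187 (33.97%). Shifting 1 list along the chromosomes 10000 times gave on average 22.99 overlapping entries of replicate 1 (2.36%) and 21.6 of replicate 2 (0.813%). The highest counts of any shift were 211 and 251. Both one-sided permutation p-values were 1e-04, the smallest that 10000 shifts can give. Many replicate 2 entries also stood in the combined list with the same coordinates and q value, and which list they came from is not given in the sources used here. Without them, a choice made after the data had been seen, 625 of the 976 replicate 1 entries (64.04%) overlapped replicate 2, and 475 of the 742 remaining replicate 2 entries (64.02%) overlapped replicate 1. Both permutation p-values were again the smallest possible. Entries with the q value of a combined region but slightly different coordinates were kept, so the remaining entries may still not rest on replicate 2 alone. Because no combined entries overlapped, at least 1 entry of each of the 460 multiply listed replicate 2 regions also remained. The remaining entries are thus a selected part of the list, and their shares do not estimate the overlap of an independent replicate 2 list.

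Regions present in replicate 1 and absent from replicate 2 numbered 6, and 1 of them had a q value below the median of the list. They lay on chromosome II at 7779291 to 7779844 (q = 1.51e-05) and 7780206 to 7781209 (q = 6.40e-07), on chromosome IV at 7162770 to 7163256 (q = 1.92e-05), 7163616 to 7164653 (q = 3.90e-05) and 8028144 to 8028535 (q = 4.92e-05), and on chromosome V at 3307321 to 3307524 (q = 5.19e-05). Being few, they are listed in full outside the rule for named regions. In coordinate numbers, 3 of the 6 overlapped a replicate 2 region of another chromosome, as did 81 of the other 752 (10.8%). Both regions on chromosome II had numbers inside the strongest region of chromosome III. The last of those on chromosome IV had the same start number as a replicate 2 region on chromosome II, at 8028144 to 8028616. Whether the chromosome names of these 3 entries are correct was not settled. Of the other 3, those at 7162770 on chromosome IV and at 3307321 on chromosome V overlapped a region of the combined list on the same chromosome. The median strength of all 6 was 4.56, against 6.08 for the 970 shared entries of replicate 1. The difference of 1.52 had a two-sided permutation p of 0.192 (100000 permutations). With a reciprocal overlap of 50% as the criterion, 32 entries were unshared and the difference of 1.30 had a permutation p of 0.0363.

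Whether a replicate 2 region was found in replicate 1 went with its strength. Shared entries of replicate 2 had a median strength of 10.5 and unshared entries one of 5.24. The difference of 5.28 had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Shared entries were also wider, with a median of 481 bp against 380 bp. When the distinct regions of replicate 2 were divided by strength into 10 groups of 218 or 219, 1.83% of the weakest group were found in replicate 1 (4 regions of 219, exact 95% interval 0.4998 to 4.61%). The share was 10.5% in the fifth group, 65.6% in the eighth and 99.5% in the strongest (218 of 219, 97.5 to 100.0%). Many of these strengths also stood in the combined list and may not rest on replicate 2 alone. The rise with strength may therefore be partly built in. The region of replicate 2 with the smallest q value that was missing from replicate 1 lay on chromosome I at 1873666 to 1874315 (q = 2.16e-18), named because it was the exception. It ranked 219 among the 2187 regions.

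**Figure D2:**
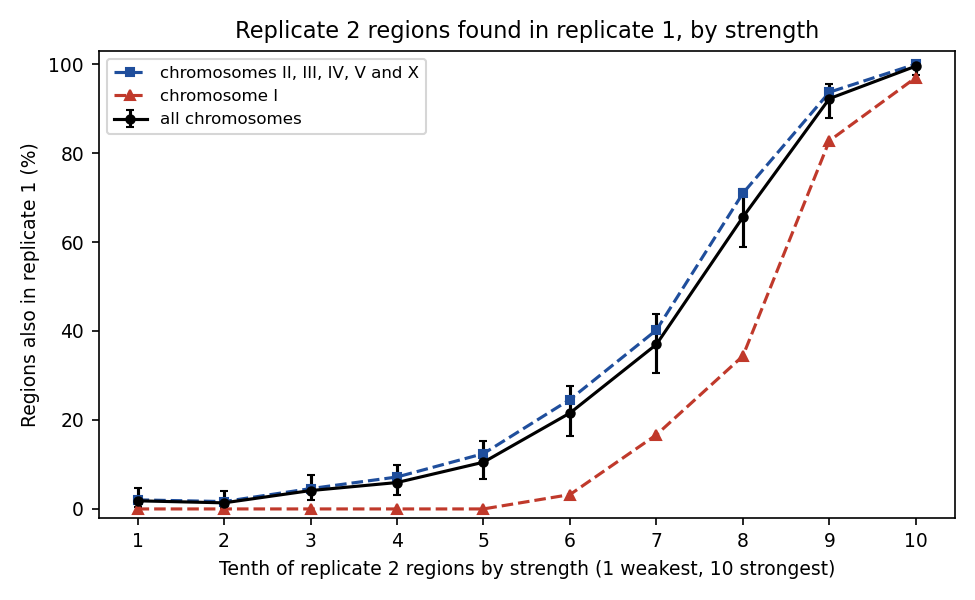
Share of distinct replicate 2 regions also present in replicate 1 (percent), for 10 groups of rising strength. Black points are all chromosomes with exact 95% binomial intervals, blue squares are chromosomes II, III, IV, V and X, and red triangles are chromosome I. The share rises from 1.83% in the weakest group to 99.5% in the strongest, and chromosome I lies below the others in every group. Strengths are those of the replicate 2 list, many of which also stand in the combined list.

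Strengths of shared regions rose together in the 2 replicate lists. Among 329 pairs of entries that overlapped each other and no other entry, Pearson's r of the strengths was 0.613 and Spearman's rho 0.603. Among 736 such pairs of distinct regions the values were 0.926 and 0.801. Each had a permutation p of 1e-05, the smallest possible. Without the 2 pairs farthest from the median on the replicate 2 axis, r was 0.599 and 0.914. These correlations run across regions, which are not independent replicates. In 2031 of the 2261 combined regions the q value equalled the smallest of the overlapping replicate 2 entries. The replicate 2 strengths may therefore not rest on replicate 2 alone, and the correlations do not measure agreement of independent replicates. In 723 of the 736 pairs (98.2%) the strength listed in replicate 1 was the lower, with a median ratio of 0.495. The depth of the libraries is unknown, and the replicate 2 strengths may be those of the combined list. This ratio therefore measures neither a change in binding nor a weaker replicate 1.

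**Figure D3:**
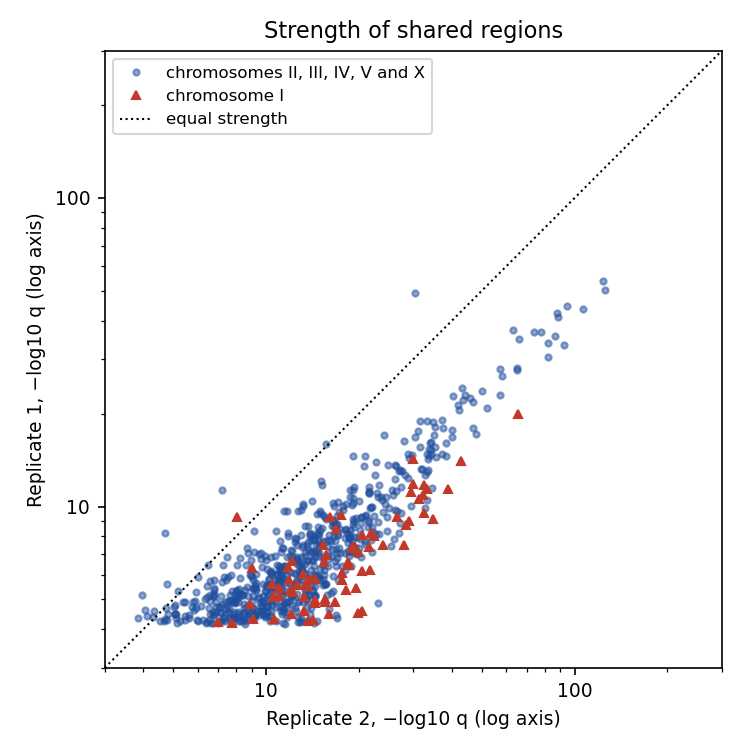
Strength (−log10 of the authors' q value) in replicate 1 against replicate 2 for the 736 pairs of shared distinct regions, both axes on a log scale. Blue circles are chromosomes II, III, IV, V and X, red triangles are chromosome I and the dotted line marks equal strength. Of the 736 points, 723 lie below the line. The replicate 2 strengths may be those of the combined list.

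The combined list was compared with the replicate lists to find how many of its regions they held. Of its 2261 regions, 743 overlapped an entry in both replicates, or 32.9% (exact 95% interval 30.9 to 34.8%). A further 1436 (63.5%, 61.5 to 65.5%) overlapped replicate 2 alone, 2 (0.0885%) overlapped replicate 1 alone, and 80 (3.54%, 2.82 to 4.38%) overlapped neither. Regions in both lists were the strong ones, with a median q value of 4.18e-14, against 4.91e-06 for those in replicate 2 alone. The 100 strongest regions were all in both lists, as were 469 of the 500 strongest (93.8%) and 675 of the 1000 strongest (67.5%). With a reciprocal overlap of 50% the counts were 91, 440 and 635. Among the 1130 strongest, the share in both was 61.8%. The 80 regions in neither list had q values from 8.30e-05 to 0.000189. In coordinates and q value together, 1910 combined regions (84.5%) were identical to an entry of replicate 2 and 0 to an entry of replicate 1. In 2031 of the 2261, the q value equalled the smallest of the overlapping replicate 2 entries. Which of the 2 lists these entries were first called in is not given in the sources used here, so neither list can be read as independent of the other, and the replicate 2 list cannot be taken to rest on replicate 2 alone.

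MAB-5 regions numbered between 317 and 411 per chromosome. Chromosome I held 317 (14.02%), II 347 (15.3%), III 402 (17.8%), IV 411 (18.2%), V 385 (17.03%) and X 399 (17.6%, exact 95% interval 16.1 to 19.3%). Among the 743 regions in both replicate lists the share of X was 19.5%. Chromosome lengths of this build were not used here, so these shares were not tested against length. No chromosome had a detectably different share among the 1130 strongest regions than among the rest, the lowest adjusted p over 6 two-sided Fisher exact tests being 0.782.

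On the autosomes, MAB-5 regions were concentrated towards the chromosome centres, and on X they were not. Of the 1862 autosomal regions, 1165 had their centre in the middle 50% of the span between the first and the last listed base, or 62.6% (60.3 to 64.8%, two-sided exact binomial p = 1.43e-27 against 50%). On X the share was 196 of 399, or 49.1% (44.1 to 54.1%, exact binomial p = 0.764). The autosomal share was 13.4 percentage points higher than that of X (two-sided Fisher exact p = 8.77e-07). Every autosome lay above 50%, from 59.1% on chromosome IV to 69.1% on chromosome V, with a largest adjusted p of 0.000872 among the 5. Autosomal regions in the middle were slightly weaker than those outside it, with median strengths of 6.20 and 6.86 (two-sided permutation p = 0.00625). Genes of this species are denser in the autosome centres than in the arms, and the shares were not corrected for gene density.

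**Figure D4:**
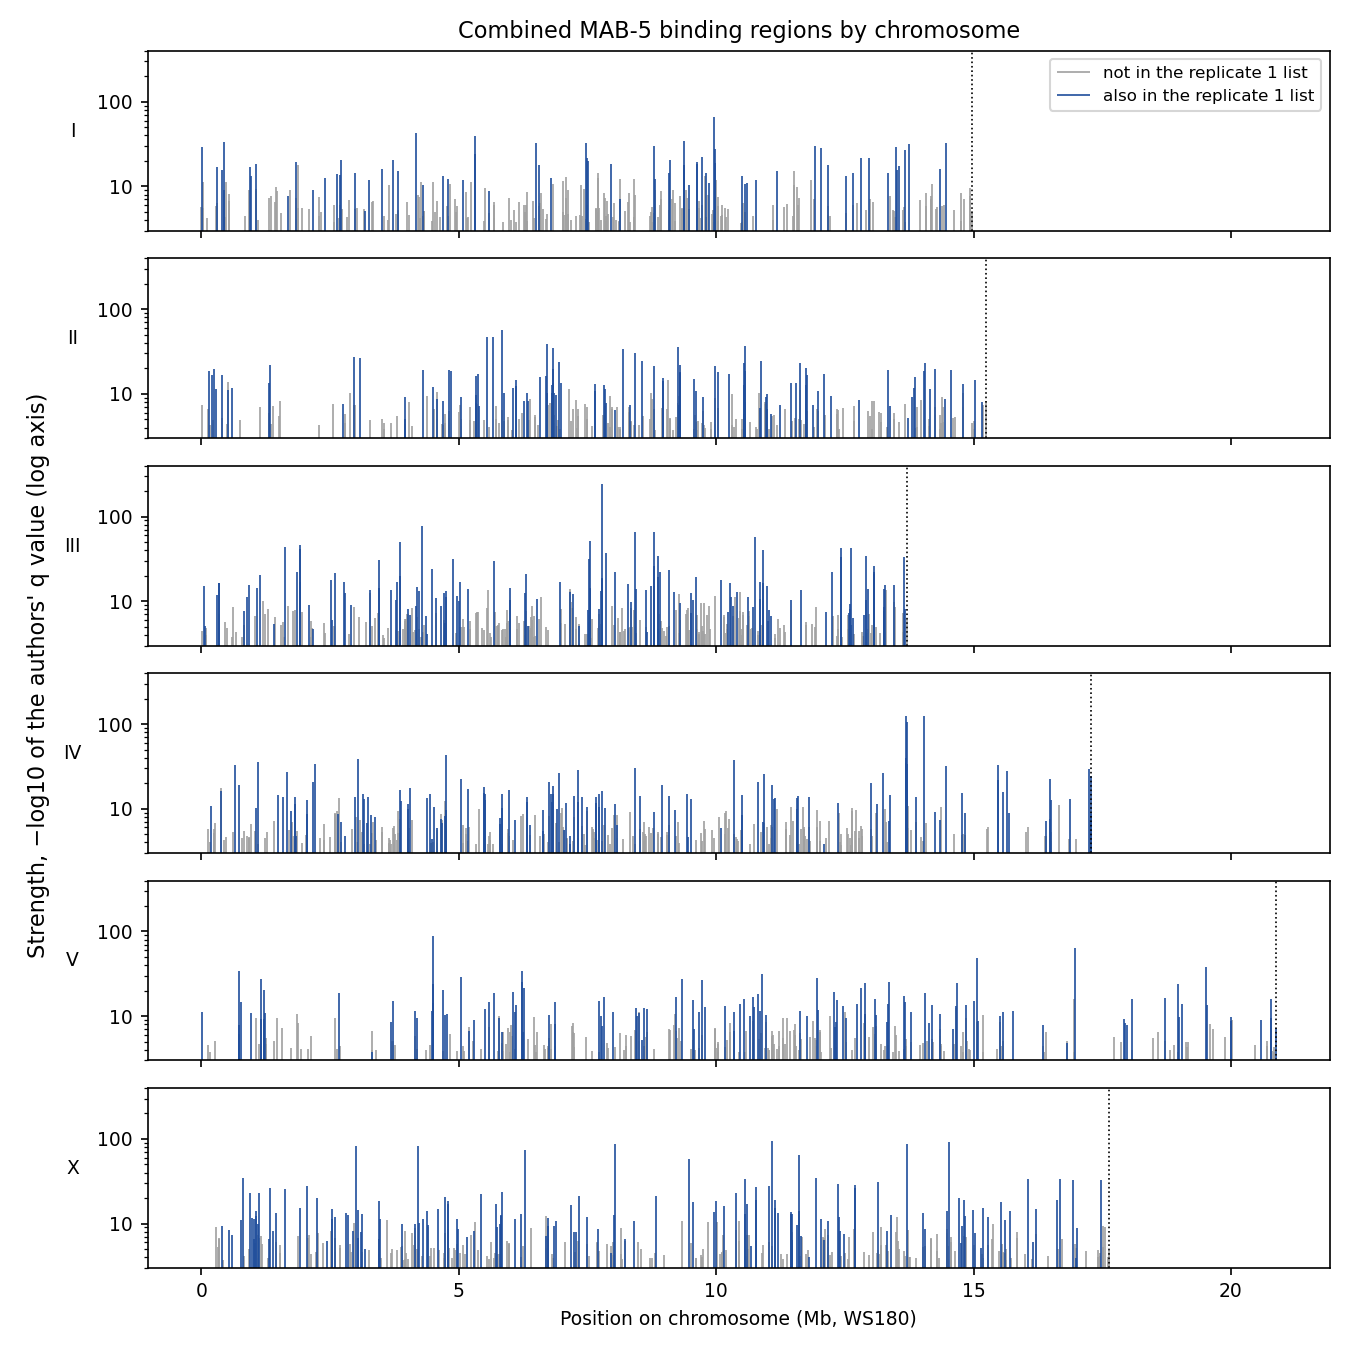
All 2261 combined MAB-5 regions by position on each chromosome (Mb, WS180), with line height showing strength as −log10 of the authors' q value on a log axis. Blue lines are regions also in the replicate 1 list, grey lines are regions that are not, and the dotted line marks the last base of any list. The tallest line, at a strength of 241, is the region on chromosome III.

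MAB-5 regions often lay close together. Of the 2255 gaps between neighbouring regions, 545 (24.2%) were 5000 bp or shorter. When each region was placed at random within its own 1 Mb window, 304.5 gaps (13.5%) were that short on average and 352 at most. The excess was 1.79-fold (one-sided permutation p = 0.001, the smallest that 1000 placements can give). In the shorter replicate 1 list alone, 14.1% of gaps were that short, against 5.23% on average in random placement, a 2.69-fold excess. Gene density within the windows was not corrected for. Joining regions no more than 5000 bp apart gave 12 clusters of at least 5 regions, where random placement gave 3.06 on average and 7 at most. This count depended on the gap allowed. With gaps of 2000 bp there were 5 clusters, against 2.32 on average and 6 at most in random placement (one-sided permutation p = 0.00699), and with gaps of 10000 bp there were 26, against 8.42 and 18. The largest cluster lay on chromosome II at 6820322 to 6849650, with 16 regions in 29.3 kb. The next was the stretch around the strongest region, on chromosome III at 7765919 to 7793253, with 10 regions in 27.3 kb. A cluster on chromosome II at 10537911 to 10563674 held 9 regions, and a cluster on chromosome IV at 13689309 to 13704419 held 7, among them the regions ranked 2 and 4 in strength. The number of such clusters followed the length of the list, with 12 in replicate 2 and 3 in replicate 1. Clusters and spacing were examined after the data had been seen.

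Regions on chromosome I were found in replicate 1 less often than regions elsewhere. Of the 309 distinct replicate 2 regions on chromosome I, 73 were found in replicate 1, or 23.6% (exact 95% interval 18.9996 to 28.8%), against 670 of 1878 (35.7%) on the other chromosomes. The two-sided Fisher exact p was 2.42e-05, and 0.000145 after adjustment over 6 chromosomes. For each of the other 5 chromosomes the adjusted p was 0.249 or higher. Median strength of the replicate 2 regions was 6.59 on chromosome I, within the range of 6.30 to 6.81 over the other chromosomes. In doubly listed regions of the replicate 2 list the weaker entry had a median of 0.280 of the strength of the stronger on chromosome I and 0.351 elsewhere. In the replicate 1 list the medians were 0.486 and 0.533. These comparisons, too, were chosen after the data had been seen.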

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

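The use of distinct regions, the removal of shared replicate 2 entries and the tests of spacing and of chromosome I were chosen after the results had been seen, and the other alternatives before. With a reciprocal overlap of 50%, the share of replicate 1 entries found in replicate 2 was 96.7%, that of replicate 2 entries found in replicate 1 was 40.7%, and the difference in strength of replicate 1 was 1.30 (permutation p = 0.0363, against 0.192), where 32 unshared entries replaced 6. With centres within 200 bp the replicate 1 share was 96.6%. Distinct regions gave 33.97% for replicate 2, where 743 shared and 1444 unshared regions replaced 1137 and 1515 entries. Without the replicate 2 entries that also stood in the combined list, 64.04% of replicate 1 entries were found in replicate 2 and 64.02% of the remaining replicate 2 entries in replicate 1. There 742 entries replaced 2652, many of them further entries of multiply listed regions. The 50% of the combined list with the smallest q values had 61.8% of its regions in both replicates, since shared regions were those with the smaller q values. The share of X was 19.5% among regions in both lists, the cause of which was not tested, and 17.6 and 19.3% without replicate 1 or 2. The overlap, correlation, centre, spacing and chromosome I results and the strength difference of replicate 2 kept their direction and their side of 0.05 under the alternatives that gave a test. The centre share ranged from 58.2 to 61.9% for the middle 50% and was 42.7% for the middle 33.3%. The excess of short gaps ranged from 1.41-fold with gaps of 10000 bp to 2.69-fold without replicate 2. The chromosome I difference ranged from -11.4 to -18.8 percentage points. The gene start, motif and gene list alternatives were not run, since no annotation of build WS180 was used. No paired analysis was possible because the lists hold no value per input sample, so ChIP and input samples with shared replicate numbers were not compared. Unknown depth limits every comparison between the replicate lists.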

Other observations

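The tests in this part were chosen after the results had been seen, apart from the count of entries over any base. Chromosome III held 4 of the 12 clusters of MAB-5 regions within 272.7 kb, from 7520603 to 7793253. This stretch contained 33 combined regions, 13 of them also in replicate 1. Its ends were set by the clusters themselves, so its density was not tested against other stretches. The worm Hox genes lin-39, ceh-13, mab-5 and egl-5 lie near each other on chromosome III, but their positions in build WS180 were not used here and no region was assigned to them. Of the 100 strongest regions, 11 lay in a cluster of at least 5, but 5 of these were in the single cluster on chromosome IV at 13689309 to 13704419. Without that cluster, 6 of 95 did, against 78 of the other 2159 (two-sided Fisher exact p = 0.165). Of the 10 strongest, 2 of the 8 outside it lay in a cluster, against 82 of the other 2246 (Fisher exact p = 0.0332). Regions of a cluster are not independent.

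Wide regions were mostly strong, and replicate 1 often covered only a part of them. Of the 25 combined regions over 2000 bp, 21 (84%) overlapped both replicate lists by at least 1 bp, a criterion that favours wide regions, against 722 of the other 2236 (32.3%). With a reciprocal overlap of 50% the counts were 9 (36%) and 693 (31.0%), and the shares did not differ detectably (two-sided Fisher exact p = 0.664). Median strengths were 25.5 and 6.43, and whether width by itself lowers the q value was not tested. After the strongest region the widest were on chromosome V at 723827 to 727802 (3976 bp, q = 2.99e-35) and on chromosome I at 9378929 to 9382165 (3237 bp, q = 1.52e-35). A wide region on chromosome II at 9059750 to 9062512 (2763 bp, q = 4.16e-15) was absent from replicate 1. Of the 13 pairs with the greater strength in replicate 1, the farthest out was on chromosome II at 8418699 to 8421554, with a strength of 49.3 there and 30.4 in replicate 2. The next, on chromosome IV at 13353219 to 13353720, had strengths of 11.3 and 7.18. Of the 80 combined regions in neither replicate list, 76 had a q value above the largest of replicate 2, 0.000148.

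Replicate 2 regions on chromosome I were found in replicate 1 less often than those elsewhere. A local gap in the replicate 1 list on chromosome I was argued against, since the share lay below that of the other chromosomes in 7 of 8 bins of 2 Mb. Strengths scaled differently by chromosome between calls may contribute. Inside the replicate 2 list, the ratio of the weaker to the stronger entry of doubly listed regions was 0.280 on chromosome I and 0.351 elsewhere, a difference of -0.0712 (one-sided permutation p = 1e-05, the smallest possible). Many entries of that list also stood in the combined list, so this ratio may not rest on replicate 2 alone. In the replicate 1 list the ratio was also lower on chromosome I, at 0.486 in 14 regions against 0.533 in 204 elsewhere. Weaker regions on chromosome I stay open, since the matching on replicate 2 strength in 10 groups, which left a difference of -10.7 points (lowest of 10000 permutations -5.50, one-sided permutation p = 1e-04, the smallest possible), used those same strengths, and no biological explanation was tested.

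Many regions were listed more than once in a replicate list. The shorter entry of an overlapping pair lay inside the longer one to a median of 100% of its length. It lay fully inside in 193 of 218 pairs of replicate 1 and in 431 of 460 pairs of replicate 2. For overlapping entries, these values argue against one call that cut a region into adjoining parts. Parts that only adjoin did not enter the test. An origin as 2 calls joined in one list may account for the pattern, since the highest number of entries over any base was 2 in both lists, a test fixed before its result was seen. The weaker entry had a median of 0.529 of the strength of the stronger in 218 regions of replicate 1 and 0.347 in 460 of replicate 2. These 2 ratios need not compare like calls. In coordinates and q value, 1910 combined regions were identical to a replicate 2 entry and 0 to a replicate 1 entry. No biological explanation was tested.

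The strongest and widest region lay on chromosome III. Several neighbouring sites joined into 1 region may account for its width, since replicate 1 held 4 distinct regions inside it. Extra copies of the mab-5 locus in the tagged strain could raise the signal of a whole stretch in that strain, because the transgene carries mab-5, a gene of chromosome III. There were 9 other regions within 20 kb, against a median of 1 and a highest value of 16 around the other 99 of the 100 strongest regions, 2 of which had as many. This count cannot be told apart from dense binding around the region, because the input signal and the position of mab-5 in this build were not analysed here, and binding of MAB-5 at its own gene was not tested for the same reason.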
